A study of Arabidopsis thaliana with 46 samples.

How the data were processed

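Messenger RNA was measured in whole roots and whole shoots of single Arabidopsis plants, in WT and in lines overexpressing PLC2, PLC3, PLC5 or PLC7, with or without contact with the nutrient medium for the last 7 days. Per the labels, plants were harvested between 1 and 5 pm, RNA was extracted with a column kit and had an integrity number of at least 6.5 for roots and 9 for shoots, ERCC spike-in mix was added, and polyA RNA was sequenced on an Ion Proton. Per the submitters' processing notes, the authors used FastQC, kallisto with TAIR10 and sleuth, and gave no versions. The deposited tables hold estimated counts (est_counts, not normalized) and effective lengths per transcript, for 41763 targets of which 92 are ERCC. The same deposited tables hold TPM, computed by the authors over all targets, ERCC included. A second deposited table per sample holds the same estimated counts (largest relative difference 5.0e-06) and was not used here.

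Estimated counts were summed over the transcripts of each of 33602 loci and rounded. Symbols came from the TAIR10.1 annotation, matched by locus for 32835 loci. The authors' build is TAIR10, so no coordinates were used. ERCC targets were kept out of the gene counts. Libraries held about 5790000 to 14430000 counts. A floor of 3 counts in the smallest WT drought library corresponds to 0.479 CPM in roots and 0.806 CPM in shoots, and covers counting error only.

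Samples were grouped by the genotype, organ and treatment of their labels. The hour of harvest of each plant is not in the labels, so no comparison was adjusted for it. Python 3.11.15 with pandas 2.3.3 prepared the counts, R 4.3.3 ran the tests and matplotlib 3.10.9 drew the plots. The test was edgeR 4.0.16's quasi-likelihood F test with TMM normalization and filterByExpr, in 1 fit per organ over its 7 groups, and 1 fit over all 46 libraries for the comparison of organs. It tested 20505 genes in roots, 19097 in shoots and 21581 in both, with a common biological coefficient of variation of 0.247, 0.297 and 0.275 and 15, 17 and 32 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg within each comparison, and 0.05 was the threshold. The comparisons were drought against control in WT and PLC5-OE, their interaction, PLC5-OE against WT in control, each line against WT under drought, differences among the 4 lines, and the WT response in roots minus shoots. PLC2-OE, PLC3-OE and PLC7-OE have no control libraries, so their drought response was not estimated. Group means are CPM with TMM-scaled library sizes, ± SD.

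Gene lists were written before the data were examined. The 24 lists hold 469 genes: core ABA signalling; ABA synthesis, breakdown and transport; ABA-responsive and dehydration genes; aquaporins; cell division; the circadian clock; cuticular wax; expansins and root hair genes; flower markers; heat shock; iron homeostasis; jasmonate; nitrate and ammonium; phosphate starvation; phosphoinositide metabolism; photosynthesis; the PLC family; proline and raffinose; root tip markers; salicylate; senescence; stomata; suberin; and sulfur deficiency. Camera (limma 3.58.1) tested each list with the preset correlation of 0.01, in 408 tests over 17 comparisons, of which 68 had an adjusted p under 0.05. With an estimated correlation 0 of these held, the lowest adjusted p being 0.0517, so list calls rest on the preset.

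Genes were named by a rule set before the data were examined. It takes the PLC genes in each comparison, and in each comparison of 2 groups the 10 largest rises and 10 largest falls with an adjusted p under 0.05, a mean of at least 1 log2 CPM and no overlap of the groups' libraries (for interactions, without the condition on overlap). It also takes up to 4 members of each described list with the smallest p. Genes at 0 counts in a group are given as at least a fold, against 3 counts in the smallest library of that group.

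The pipeline was tested on simulated data with the design of these libraries and 100 genes changed at each of 2 sizes. In the WT root comparison edgeR recovered 52% of genes changed 2-fold and 98% changed 4-fold, with 5 false among 155 calls, and DESeq2 61% and 99%, with 22 false among 182. With 2 against 4 libraries, as for PLC7-OE roots, edgeR recovered 33% and 88% (7 false of 128), and for the root interaction 14% and 78% (4 false of 96). Camera found a raised list of 40 genes and called 0 of 24 unchanged lists. The simulated genes were drawn independently of each other, so this does not test false calls in lists whose members move together.

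Alternatives set before the data were examined were size factors from medians of ratios (RLE), DESeq2 1.42.0, no low-count filter, only the groups compared in the fit, the replicate number as a block, offsets for transcript length, a limit of 2-fold, no organelle genes, scaling to ERCC counts, TPM for the PLC levels, and each library left out in turn. Chosen after seeing the data were the log2 ERCC share as a covariate, removal of the trend with transcript length from each library, the omission of libraries over 5% ERCC, and the omission of both libraries with a second PLC. Replicate numbers did not pair the libraries: after removal of group means, libraries of 1 number had a median correlation of 0 in roots and -0.03 in shoots. No library duplicated another of its own group, with a chi-square per gene of at least 6.7 in 55 pairs; pairs between groups were not compared. Transcript isoforms and the raw reads were not analysed here.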

Results

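Messenger RNA was sequenced from whole roots and whole shoots of Arabidopsis thaliana, in wild-type plants (WT) and in lines that overexpress 1 of 4 genes of phosphoinositide-specific phospholipase C (PLC). This enzyme splits phosphoinositides of the plasma membrane into diacylglycerol and soluble inositol phosphates. Plants had spent 9 days on agar and 12 days on vermiculite, and for the next 7 days they either kept contact with the nutrient medium (control) or were cut off from it (drought). Loss of contact withdraws water and dissolved nutrients together. The 46 libraries, 22 of root and 24 of shoot, form 14 groups of 2 to 4. WT has 4 libraries in each of its 4 groups, and the PLC5 overexpressor (PLC5-OE) has 4 in control shoots and 3 in each other group. PLC2-OE, PLC3-OE and PLC7-OE were sampled under drought alone, with 3 libraries per tissue, except 2 for PLC7-OE roots. The study asks how a raised level of a PLC changes the transcript response to drought.

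Libraries held about 5790000 to 14430000 estimated counts, with a median of 9270000. The same spike-in mix of ERCC control RNAs had been added to the samples, and its share differed between groups. It was 13.26 ± 2.33% of counts in WT drought shoots (SD, n = 4) and 2.88 ± 2.6% in WT control shoots (n = 4), a difference with p = 0.0286 in an exact two-sided permutation test, the smallest p that 70 splits allow. In WT roots it was 10.7 ± 4.71% under drought and 6.43 ± 8.87% in control (n = 4 each; p = 0.4 in the same exact test). Drought groups of the overexpressors had means from 1.56% in PLC2-OE roots to 6.3% in PLC5-OE shoots. Every comparison of an overexpressor with WT under drought therefore also compares libraries of lower and higher ERCC share. In drought roots the share was at least 7.7% in WT and at most 2.5% in PLC2-OE, PLC3-OE and PLC7-OE. In drought shoots it was at least 9.88% in WT and at most 6.02% in these lines. A fit with the share as a covariate can hardly tell line and share apart there. Fewer calls in it are no evidence that the share is the cause. Fold changes are relative to the other genes of a library: with libraries scaled to the ERCC counts instead, the median of all genes moved by -2.17 (roots) and -3.34 (shoots) on the log2 scale in the WT drought comparisons and by 1.25 to 3.5 in those of the lines with WT.

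Each overexpressor held more transcript of its own PLC than any WT library of the same tissue, in 30 of 30 overexpressor libraries. PLC3 stood at 925 ± 303 CPM in PLC3-OE drought roots (SD, n = 3) and 9.18 ± 3.86 CPM in WT drought roots (n = 4), and at 1350 ± 267 against 1.85 ± 1.04 CPM in shoots. PLC5 stood at 310 ± 15.2 CPM in PLC5-OE drought roots (n = 3) against 10.3 ± 2.8 CPM in WT, and at 327 ± 36.9 against 0.845 ± 0.373 CPM in shoots. PLC2, which WT expresses at the highest level of the family, reached 439 ± 46.1 CPM in PLC2-OE drought roots (n = 3) against 130 ± 16 CPM in WT (n = 4), and 432 ± 80.2 against 240 ± 48.8 CPM in shoots. PLC7 reached 149 ± 1.5 CPM in PLC7-OE drought shoots (n = 3) and 182 ± 2.12 CPM in PLC7-OE drought roots (n = 2). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PLC7 was the single overexpressed gene that did not pass against WT, in PLC7-OE roots. The library labelled WT root drought 3 held 118 CPM of PLC7, while the other 3 WT drought roots held 1 to 2.76 CPM. Without that library the PLC7-OE mean was 89.1 times the WT mean, and with it 5.87 times. A second library, labelled PLC3-OE root drought 1, held 107 CPM of PLC5, while the other PLC3-OE roots started at 16.7 CPM.

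**Figure D1:**
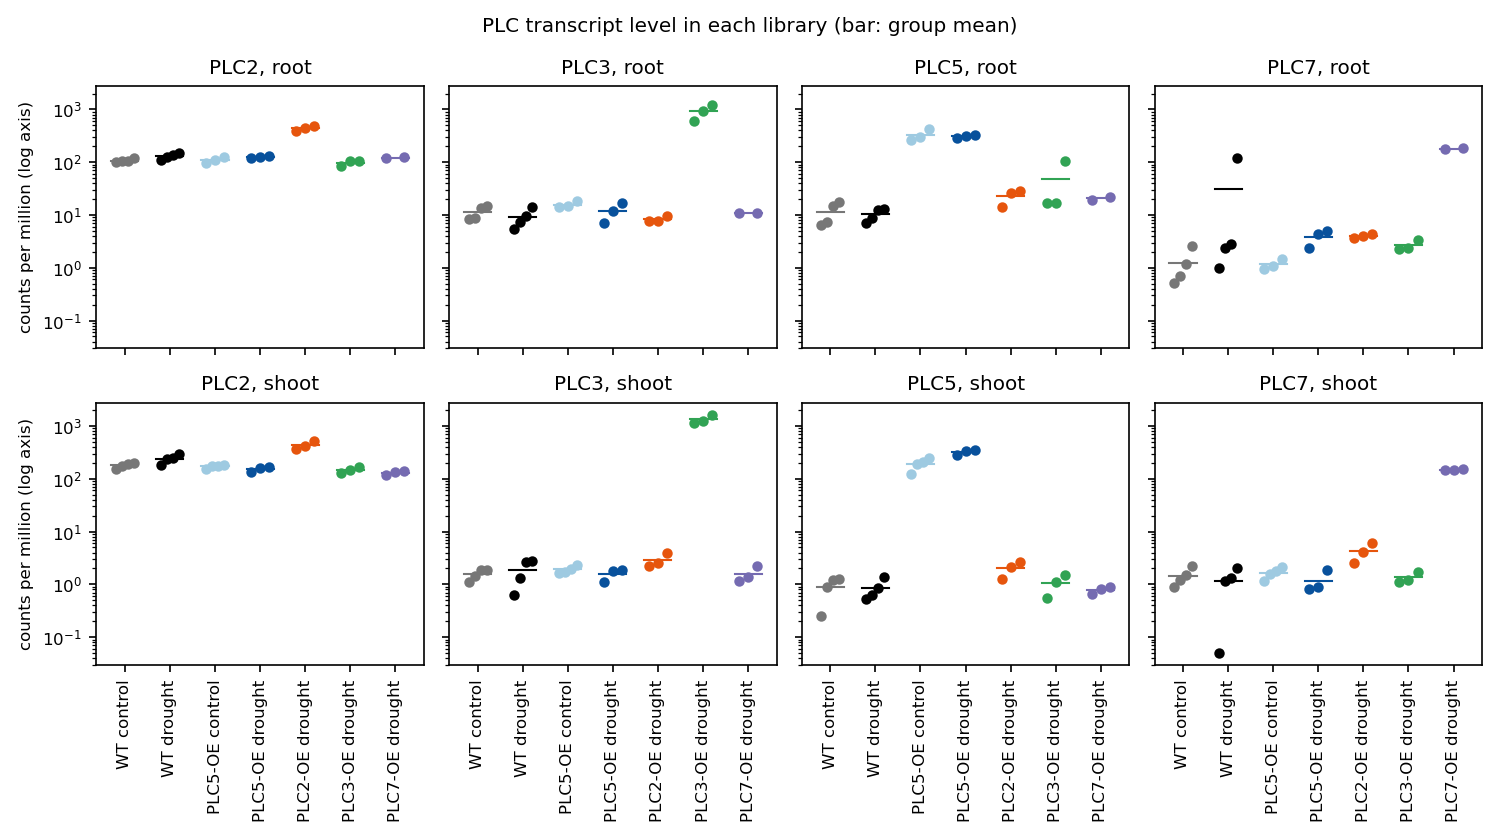
Transcript level of PLC2, PLC3, PLC5 and PLC7 in each library, in CPM on a log axis, by genotype and treatment, with root in the upper and shoot in the lower panels. Dots are libraries, bars are group means, and 1 library with no PLC7 count is drawn at the bottom of its panel. In each panel the line that overexpresses the gene lies above all WT libraries, and the WT root drought library at 118 CPM of PLC7 lies far above its group.

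Drought in WT roots went with more transcript of genes for sulfate and iron acquisition. LSU1, a gene of the response to low sulfur, stood at 49.1 ± 28.1 CPM under drought and 0.429 ± 0.53 CPM in control roots (SD, n = 4 each), a log2 fold change of 7.04 ± 0.69 (SE). Of 11 tested genes of the sulfur deficiency list, 9 rose and 0 fell, and 9 when adjusted over the list alone. Among them SULTR1;2, the main root sulfate transporter, went from 131 ± 18 to 317 ± 51 CPM, and APR3, an enzyme of sulfate reduction, from 79 ± 44.9 to 307 ± 66.9 CPM. Of 19 iron homeostasis genes, 10 rose and 1 fell, and 12 and 1 when adjusted over the list alone. The nicotianamine synthase gene NAS4 rose from 2.51 ± 0.788 to 30.1 ± 19.4 CPM, and the iron deficiency genes IMA1 and BHLH38 rose by log2 5.86 ± 1.27 and 5.09 ± 1.14. BTS, whose product restrains the iron uptake response, fell from 43.6 ± 9.13 to 21.7 ± 9.88 CPM. The largest rises were in AT1G34047 (2650 ± 2340 against 5.96 ± 5.36 CPM), AT2G36255 (601 ± 519 against 3.39 ± 2.97 CPM) and AT2G36260 (15 ± 16.4 against 0.0846 ± 0.1 CPM), and the zinc transporter gene MTPA1 also rose, from 0.412 ± 0.713 to 30 ± 36.5 CPM. The largest falls were in AT1G25472 (-6.43 ± 1.81 on the log2 scale), AT5G26130 (1.81 ± 1.41 against 47.2 ± 27.6 CPM) and the sugar transporter gene STP14 (0.444 ± 0.359 against 8.74 ± 2.92 CPM). The haemoglobin gene HB1 fell by 3.02 on the log2 scale.

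In that comparison camera, which tests whether a list moves more than other genes, called sulfur deficiency (adjusted p = 1.44e-08, and adjusted p = 0.4 with an estimated correlation) and iron homeostasis (adjusted p = 0.0106, and adjusted p = 0.803 with an estimated correlation). It also called the nuclear photosynthesis genes, with 0 of 35 past the threshold, 0 adjusted over the list alone and a median log2 fold change of 0.94 (adjusted p = 0.0156, and adjusted p = 0.89 with an estimated correlation). The mean of these genes in single root libraries ran from 1.91 to 6.2 log2 CPM. Lists for core ABA signalling, for ABA synthesis, breakdown and transport, and for proline and raffinose metabolism were not called (adjusted p = 0.626, 0.798 and 0.895). Neither were expansins and root hair genes, nitrate and ammonium uptake and assimilation, root tip markers or flower markers (adjusted p = 0.647, 0.747, 0.712 and 0.564). These 7 lists were called in none of the 17 comparisons. At an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2770 of 20505 genes rose and 3112 fell, 5882 in all. With the ERCC share as a covariate the count was 915, and log2 fold changes had a Spearman rho of -0.47 with transcript length across genes, which are not independent replicates. Leaving out 1 library moved the count by over 1.5 times for WT root control 1 (3884), 2 (3529) and 3 (3855) and WT root drought 4 (3517).

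Drought in PLC5-OE roots also went with rises in genes of the sulfur deficiency and iron homeostasis lists. ZIP12, a zinc transporter gene, stood at 14 ± 3.45 CPM under drought (SD, n = 3) and had 0 counts in all 3 control roots, at least 34.3-fold higher when the floor is 3 counts per library. MTPA1 rose from 1.44 ± 1.14 to 110 ± 12 CPM, and AT1G12030 from 1.46 ± 0.784 to 110 ± 30 CPM. Of 11 sulfur deficiency genes 7 rose (9 adjusted over the list alone), with LSU2 going from 11.6 ± 5.04 to 134 ± 38.7 CPM. Of 19 iron homeostasis genes 5 rose (12 adjusted over the list alone), with NAS4 going from 9.31 ± 3.44 to 133 ± 26 CPM. Of 19 circadian clock genes 6 fell and 1 rose (9 and 3 adjusted over the list alone), with LNK2 falling from 49.7 ± 13.1 to 6.52 ± 2.14 CPM and PRR9 from 7.22 ± 1.42 to 0.469 ± 0.415 CPM. Of 17 phosphate starvation genes 3 rose (5 up and 1 down adjusted over the list alone), among them PAP17, an acid phosphatase, from 3.97 ± 1.88 to 11.4 ± 0.886 CPM. The suberin and Casparian strip list had 2 of 22 members up (5 adjusted over the list alone), CYP86B1 and ABCG20, and the cell division list had 1 of 21 down (5 adjusted over the list alone), CDC20.2. AT3G62950 (0.0525 ± 0.0909 against 4.13 ± 0.672 CPM), AT5G26130 (1.06 ± 0.7 against 31.8 ± 18.9 CPM) and AT5G50530 (0 counts in all 3 drought roots against 3.47 ± 0.998 CPM, at least 6.9-fold lower) fell too.

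With camera these lists had an adjusted p = 1.31e-07 for sulfur deficiency, 1.96e-07 for iron homeostasis, 0.00129 for suberin, 0.00469 for the clock, 0.00658 for phosphate and 0.0236 for cell division. None held: adjusted p = 0.157 with an estimated correlation for sulfur, iron, clock and phosphate, 0.39 for suberin and 0.44 for cell division. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 740 genes rose and 790 fell, 1530 in all. Of the genes called in both genotypes, 1030 moved the same way and 4 the opposite way, and 219.9 would be shared by independent lists. The count was 932 with the ERCC share as a covariate, 775 and 842 without PLC5-OE root control 1 and 2, and 647 and 702 without PLC5-OE root drought 1 and 2.

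Whether the drought response of roots differs between PLC5-OE and WT was asked with an interaction term, and a single gene passed. LNK1, a clock-associated gene, had a response lower by 1.45 ± 0.22 (SE) on the log2 scale in PLC5-OE, where drought roots stood at 7.39 ± 0.433 CPM (n = 3) and control roots at 19.4 ± 2.16 CPM (n = 3). None of 23 aquaporin genes passed (5 lower adjusted over the list alone), though camera called the list with a median of -0.4 (adjusted p = 0.00148, and adjusted p = 0.749 with an estimated correlation). TIP2;3 was the nearest of them, with a difference of -1.6 ± 0.37. None of 35 photosynthesis genes passed either (0 adjusted over the list alone), with a median of -1.36 (adjusted p = 0.00736, and adjusted p = 0.749 with an estimated correlation). At an unadjusted p under 0.05 edgeR's quasi-likelihood test had 1678 of 20505 genes, and DESeq2 called 91 after adjustment. Single libraries left out gave 0 to 27 genes, the highest without WT root control 4. LNK1 (adjusted p = 0.0465) lost its call without any 1 of 8 libraries, and with RLE size factors, length offsets, the replicate number as a block, the length trend removed or these groups fitted alone.

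PLC5-OE differed from WT in few genes when both kept contact with the medium. In control roots 4 genes were higher and 0 lower: PLC5 itself (325 ± 81.4 against 11.6 ± 5.49 CPM, n = 3 and 4), AT1G34047 (261 ± 251 against 5.96 ± 5.36 CPM), the cytochrome P450 gene CYP78A6 (8.23 ± 1.48 against 3.02 ± 0.435 CPM) and SULTR1;2 (240 ± 23 against 131 ± 18 CPM). In control shoots PLC5 was higher (194 ± 53.9 against 0.902 ± 0.467 CPM, n = 4 each) and AT1G78170 lower (0.0207 ± 0.0415 against 6.27 ± 1.77 CPM). These were the calls of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with an adjusted p = 0.0419 for AT1G34047, CYP78A6 and SULTR1;2, 0.000284 for PLC5 in roots, 8.05e-12 for PLC5 in shoots and 3.69e-07 for AT1G78170. At an unadjusted p under 0.05 there were 798 genes in roots and 736 in shoots, and DESeq2 called 26 and 5. In roots the count went from 1 to 17 as single libraries were left out: 1 without WT root control 1 or 3 or PLC5-OE root control 1 or 3, 2 without WT root control 2 or 4, and 17 without PLC5-OE root control 2. It was 0 without libraries over 5% ERCC, which removes PLC5 from the called genes, although its level in each PLC5-OE root library stayed above all WT root libraries.

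Camera called several lists in the same control comparisons without a member past the threshold over all genes or adjusted over the list alone. In roots these were ABA-responsive and dehydration genes (0 of 24, median -0.41, adjusted p = 2.08e-05, and adjusted p = 0.0517 with an estimated correlation) and photosynthesis (0 of 35, median 0.77, adjusted p = 0.0357, and adjusted p = 0.773 with an estimated correlation). In shoots they were stomata and guard cells (0 of 17, median 0.51, adjusted p = 0.00252), aquaporins (0 of 20, median -0.32, adjusted p = 0.0051), jasmonate (0 of 22, median -0.34, adjusted p = 0.027) and sulfur deficiency (0 of 11, median -0.52, adjusted p = 0.0449), each with an adjusted p = 0.772 with an estimated correlation. The guard cell genes SLAC1 and MYB60 had log2 differences of 0.68 ± 0.34 and 0.68 ± 0.32. With the ERCC share as a covariate the photosynthesis call in roots and the aquaporin, jasmonate and sulfur calls in shoots were lost. The replicate block also lost the calls of root photosynthesis and shoot sulfur, and removal of the length trend lost that of shoot sulfur. The PLC family list, called in both tissues, had PLC5 as its 1 member of 8 past either threshold, with medians of 0.15 and 0.13 (adjusted p = 0.00627 and 0.0051, and adjusted p = 0.0517 and 0.092 with an estimated correlation).

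Drought in WT shoots went with higher sulfur, water channel, dehydration and photosynthesis transcripts. Of 11 sulfur deficiency genes 8 rose (8 adjusted over the list alone), with LSU2 going from 6.65 ± 4.81 to 61.8 ± 24.3 CPM and APR3 from 29.5 ± 14.4 to 126 ± 44.6 CPM (SD, n = 4 each). Of 25 ABA-responsive and dehydration genes 7 rose (7 adjusted over the list alone), among them the dehydration marker RD29A (310 ± 82.3 to 916 ± 427 CPM), KIN2 (764 ± 185 to 2870 ± 1570 CPM) and ATHB12 (4.12 ± 1.68 to 14.5 ± 2.98 CPM). Of 20 aquaporins 8 rose (8 adjusted over the list alone), among them TIP2;2 (93.6 ± 24.5 to 327 ± 114 CPM) and PIP1;2 (575 ± 250 to 1490 ± 401 CPM). Of 35 photosynthesis genes 16 rose (20 up and 1 down adjusted over the list alone), with the photosystem I subunit gene PSAG going from 2200 ± 543 to 6250 ± 2080 CPM. The mean log2 CPM of this list was above all control shoots in WT shoot drought 1, 2 and 3 but 11.46 in 4, against 11.82 to 11.88 in WT shoot control 1 to 3 and 11.36 in 4, which lay apart from its group. The zinc transporter genes ZIP9 and ZIP3 rose by log2 5.55 ± 0.83 and 3.9. AT1G34047 stood at 9.65 ± 16.4 CPM and had 0 counts in all 4 control shoots (at least 25.7-fold higher), and MPC rose from 0.276 ± 0.111 to 14.6 ± 14.8 CPM. The asparagine synthetase gene ASN1 fell from 137 ± 34.5 to 5.58 ± 1.99 CPM, and the proline dehydrogenase gene PRODH1 and the sugar starvation gene DIN10 fell by 3.56 and 3.63 on the log2 scale. AT4G26095 had 0 counts in all 4 drought shoots against 4.45 ± 3.11 CPM (at least 5.52-fold lower), and AT1G05090 fell from 4.46 ± 3.21 to 0.202 ± 0.403 CPM.

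Camera gave an adjusted p = 0.000459 for sulfur deficiency, 0.0158 for ABA-responsive genes, 0.0196 for aquaporins and 9.15e-05 for photosynthesis, and an adjusted p = 0.765 with an estimated correlation for each. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 3141 of 19097 genes rose and 3467 fell, 6608 in all. With the ERCC share as a covariate the count was 860, the ABA-responsive and aquaporin lists lost their calls (adjusted p = 0.637 and 0.0584), and 0 photosynthesis genes passed. Log2 fold changes had a rho of -0.47 with transcript length across genes, and 4328 genes were called when these groups were fitted alone.

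Drought in PLC5-OE shoots went with lower photosynthesis transcripts. Of 35 genes 23 fell and 0 rose (29 down adjusted over the list alone), led by the light-harvesting genes LHCB2.1 (4030 ± 1070 to 273 ± 155 CPM, n = 4 and 3), LHCB2.2 (3800 ± 1300 to 332 ± 171 CPM) and LHCA4 (6250 ± 786 to 1660 ± 489 CPM). Of 19 salicylate and defence genes 6 rose (10 adjusted over the list alone), among them the pathogenesis-related genes PR1 (47.1 ± 22.5 to 802 ± 794 CPM) and PR2 (262 ± 157 to 2400 ± 768 CPM). Of 10 heat shock genes 6 rose (7 adjusted over the list alone), among them the heat shock factor gene HSFA2 (0.358 ± 0.404 to 4.74 ± 3.26 CPM). Of 19 clock genes 8 fell and 3 rose (8 and 4 adjusted over the list alone): PRR5 went from 123 ± 11.4 to 17.7 ± 2.77 CPM, and BOA from 1.88 ± 0.857 to 24.9 ± 0.811 CPM. Among the largest rises were the metal transporter gene ZIP9, going from 0.486 ± 0.509 to 210 ± 87.8 CPM, the citrate transporter gene FRD3 from 0.156 ± 0.162 to 14.5 ± 7.32 CPM, and the nicotianamine synthase gene NAS2 rising by log2 5.79. AT1G56242 stood at 6.92 ± 4.91 CPM with 0 counts in all 4 control shoots (at least 22.1-fold higher), and AT4G11393 rose from 0.46 ± 0.386 to 168 ± 142 CPM. AT5G35777 had 0 counts in all 3 drought shoots against 10.7 ± 1.45 CPM (at least 27-fold lower), AT2G29300 fell from 7.97 ± 2.25 to 0.0246 ± 0.0426 CPM, and the protein kinase gene CIPK20 fell from 13.5 ± 3.34 to 0.164 ± 0.0932 CPM. The superoxide dismutase gene CSD2 fell from 567 ± 140 to 10.9 ± 1.12 CPM and the carbonic anhydrase gene CA1 by 4.03 on the log2 scale.

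These lists had in camera an adjusted p = 1.53e-16 for photosynthesis, 6.84e-05 for salicylate, 0.00441 for heat shock and 0.0434 for the clock, and an adjusted p = 0.963 with an estimated correlation for each. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2077 genes rose and 1987 fell, 4064 in all. The count was 734 with the ERCC share as a covariate, 2341 without libraries over 5% ERCC, 2553 without PLC5-OE shoot control 4, and 2402 and 2229 without PLC5-OE shoot drought 1 and 3. Of genes called in both genotypes 1757 moved the same way and 104 the opposite way, and 702.4 would be shared by independent lists.

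The interaction term asked which shoot genes answered drought differently in PLC5-OE and WT, and photosynthesis genes led it. Of 35 photosynthesis genes 31 had a lower response in PLC5-OE and 0 a higher one (35 adjusted over the list alone), with a median of -2 on the log2 scale, LHCB2.1 at -4.39 ± 0.64, LHCB4.2 at -3.04 ± 0.47 and LHCB6 at -2.71 ± 0.51. Of 20 aquaporins 5 had a lower response (9 adjusted over the list alone), among them TIP2;2 at -1.74 ± 0.36 and PIP1;2 at -1.66 ± 0.44. Of 19 clock genes 6 had a lower and 1 a higher response (8 and 3 adjusted over the list alone), with PRR5 at -2.82 ± 0.27 and BOA at 3.75 ± 0.57. None of 22 jasmonate genes passed (0 adjusted over the list alone), with a median of 1.55. The largest positive differences were in CYP94B1, which inactivates jasmonate (9.31 ± 2.43), AT4G11393 (6.79 ± 1.69) and ELI3-2 (5.87 ± 1.63). Among the negative ones were CIPK20 (-7.81 ± 0.78), AT2G29300 (-6.95 ± 1.15) and AT5G35777 (-6.5 ± 1.28), and the cold-response factors DREB1A and CBF2 had -5.94 ± 0.73 and -5.16. Fitted differences of genes with 0 counts in a group, such as AT5G35777, depend on the prior count of the fit.

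Camera gave an adjusted p = 3.65e-31 for photosynthesis, 5.65e-05 for aquaporins, 0.00549 for the clock and 0.0203 for jasmonate; with an estimated correlation the adjusted p = 0.353, 0.63, 0.353 and 0.865. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 448 interactions were positive and 644 negative, 1092 in all. The count depended on single libraries. It was 1790, 668 and 400 without WT shoot control 1, 3 and 4, and 697, 713 and 523 without PLC5-OE shoot control 1, 3 and 4. It was 553, 528 and 2941 without WT shoot drought 2, 3 and 4, and 1775, 227 and 621 without PLC5-OE shoot drought 1, 2 and 3. The mean level of the list (photosynthesis, nuclear-encoded) was 12.29, 13.11, 12.68 and 11.46 log2 CPM in the 4 WT drought shoots, and 10.81, 9.56 and 10.77 in the 3 PLC5-OE drought shoots.

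**Figure D2:**
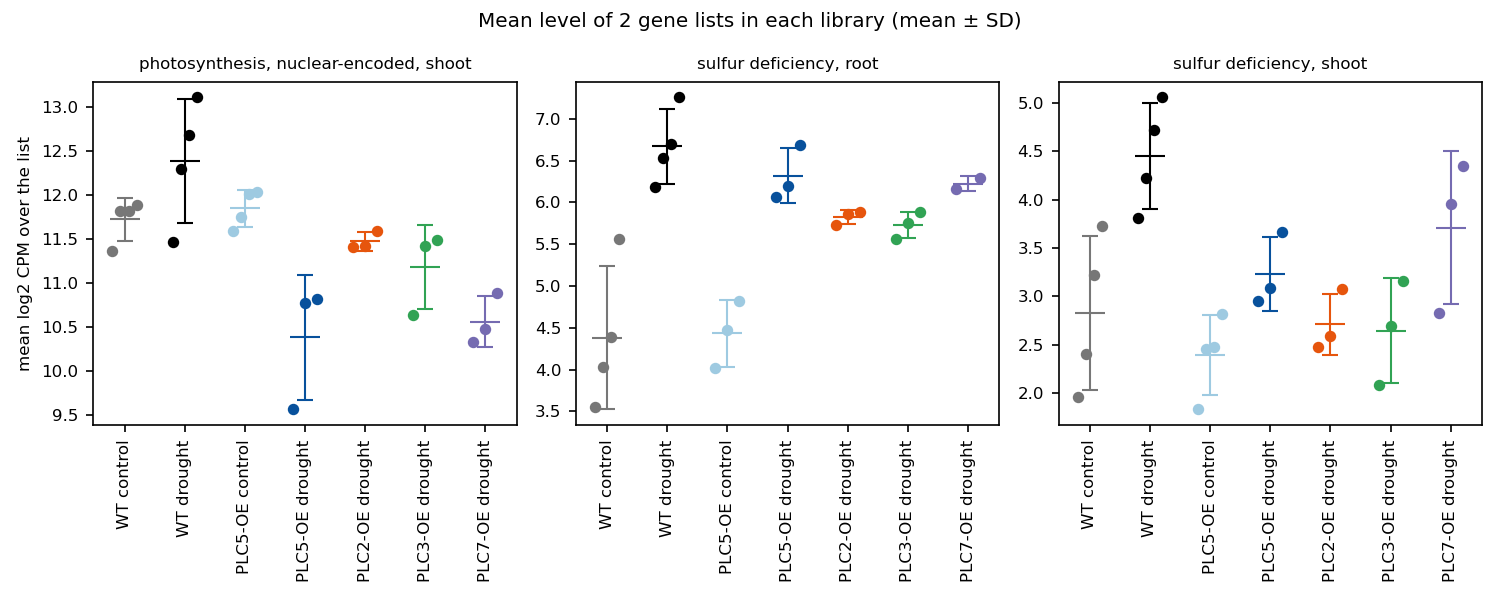
Mean log2 CPM over the genes of the photosynthesis list in shoots and of the sulfur deficiency list in roots and shoots, for each library (dots), with group means and SD (bars), by genotype and treatment. Of 4 WT drought shoots 3 lie above all control shoots in photosynthesis level and 1 at 11.46, and the PLC5-OE drought shoots lie below all control shoots.

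Under drought PLC2-OE roots held more jasmonate and phosphoinositide transcripts than WT roots. Of 21 jasmonate genes 6 were higher (8 adjusted over the list alone), among them the signalling repressor genes JAZ9 (42.2 ± 31.2 against 3.5 ± 3.29 CPM, n = 3 and 4) and JAZ10 (81.5 ± 82.4 against 6.34 ± 6.05 CPM) and the synthesis gene OPR3 (213 ± 142 against 38 ± 15.5 CPM). Of 38 phosphoinositide and inositol phosphate genes 13 were higher and 0 lower (14 adjusted over the list alone), among them the inositol phosphate kinase gene ITPK3 (27.7 ± 8.13 against 7.99 ± 2 CPM) and MIOX2, which opens the inositol ring (77.5 ± 6.83 against 27.2 ± 20.7 CPM). Of 22 suberin genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone), with FAR5 at 61.7 ± 3.83 against 26 ± 2.04 CPM and the regulator MYB92 lower. Of 23 aquaporins 6 were lower (7 adjusted over the list alone), with PIP1;3 at 1320 ± 50.5 against 2210 ± 92.6 CPM. The microRNA precursor MIR398c stood at 5.26 ± 3.32 CPM with 0 counts in all 4 WT drought roots (at least 11-fold higher), CYP705A16 at 2.79 ± 2.11 against 0.0799 ± 0.16 CPM and 4CL8 at 6.89 ± 5.83 against 0.213 ± 0.0794 CPM. AT5G50150 was lower (0.0811 ± 0.071 against 21.4 ± 7.6 CPM), as were the chloroplast gene ATCG00220 (0.322 ± 0.216 against 13.3 ± 13.6 CPM) and AT5G43540 (2 ± 0.53 against 38.3 ± 6.45 CPM). These lists had in camera an adjusted p = 0.0108 for jasmonate, 0.00162 for phosphoinositides, 0.0302 for suberin and 0.0063 for aquaporins; with an estimated correlation the adjusted p = 0.894, 0.633, 0.887 and 0.887. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 2534 genes were higher and 2517 lower, 5051 in all. With the ERCC share as a covariate 5 remained in the count, 3 of them lower, and the aquaporin call was lost (adjusted p = 0.583). The shares of PLC2-OE (1.1 to 1.88%) and WT drought roots (7.7 to 17.71%) did not overlap. This fit can therefore hardly separate the line from the share. The phosphoinositide and aquaporin calls were lost with the length trend removed, and the suberin call with the replicate number as a block. The count was 3052 without WT root drought 4, and 2535 and 2793 without PLC2-OE root drought 1 and 3.

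In PLC3-OE drought roots aquaporins were again lower than in WT. Of 23 members 11 were lower (13 adjusted over the list alone), among them PIP1;3 (1150 ± 210 against 2210 ± 92.6 CPM, n = 3 and 4) and PIP2;2 (611 ± 61.1 against 1290 ± 266 CPM). Higher than in WT were PLC3, MIR398c (10.6 ± 9.14 CPM against 0 counts, at least 22.1-fold) and AT2G15780 (55.8 ± 39.4 against 3.04 ± 4.51 CPM), and the defence gene PR2 was higher too (16.7 ± 14.8 against 1.46 ± 0.896 CPM). The largest negative differences were in AT3G20760 (0.476 ± 0.132 against 14.1 ± 13.9 CPM), ATCG00220 (0.535 ± 0.466 against 13.3 ± 13.6 CPM) and the small nucleolar RNA gene U3D (6.03 ± 3.34 against 110 ± 33.4 CPM). Camera gave aquaporins an adjusted p = 0.000175, and adjusted p = 0.763 with an estimated correlation. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3190 genes were higher and 2991 lower, 6181 in all. The count was 2 with the ERCC share as a covariate, 3954 without PLC3-OE root drought 3, and 3474 without both libraries that hold a second PLC.

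PLC5-OE drought roots differed from WT in iron homeostasis genes and in single genes such as ZIP12. ZIP12 stood at 14 ± 3.45 against 0.402 ± 0.609 CPM (n = 3 and 4), and of 19 iron homeostasis genes 3 were higher (3 up and 1 down adjusted over the list alone): NAS4 (133 ± 26 against 30.1 ± 19.4 CPM), F6H1, which makes iron-binding coumarins (177 ± 25.5 against 61.7 ± 36.7 CPM), and FIT, the main regulator of iron uptake (41.1 ± 5.36 against 18.8 ± 9.88 CPM). MIR398c stood at 33.3 ± 9.87 CPM against 0 counts in WT (at least 69.5-fold), and the copper/zinc superoxide dismutase gene CSD1 was lower by 2.24 on the log2 scale. Of 23 aquaporins 2 were lower, TIP2;3 (155 ± 35.1 against 487 ± 120 CPM) and PIP1;3 (8 adjusted over the list alone). PLC5 was the 1 member of 8 PLC genes that was higher (2 up and 1 down adjusted over the list alone). None of 21 cell division and 38 phosphoinositide genes passed (0 adjusted over each list alone), with medians of -0.21 and 0.24. The first negative differences were in AT3G62950 (0.0525 ± 0.0909 against 1.17 ± 0.469 CPM), OXS3 (3.24 ± 0.776 against 23.1 ± 18.5 CPM) and AT5G02090 (18.3 ± 4.12 against 103 ± 59.6 CPM). Camera gave an adjusted p = 0.000592 for iron, 5.13e-05 for aquaporins, and 0.0253 for cell division and for phosphoinositides; the adjusted p = 0.537 with an estimated correlation for each. The PLC family had an adjusted p = 0.0372, and adjusted p = 0.354 with an estimated correlation. The phosphoinositide call was lost with the ERCC share as a covariate. It was also lost with the length trend removed, as was the PLC family call. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 183 genes were higher and 157 lower, 340 in all. The count was 75 with the ERCC share as a covariate, 639 and 113 without WT root drought 2 and 3, 65 and 29 without PLC5-OE root drought 2 and 3, and 864 with DESeq2. It was 45 with these groups fitted alone and 89 without both libraries that hold a second PLC.

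PLC7-OE drought roots, with 2 libraries, showed lower aquaporin transcripts than WT. Of 23 aquaporins 10 were lower (14 adjusted over the list alone), among them PIP2;3 (13.7 ± 0.445 against 70.2 ± 27.8 CPM, n = 2 and 4) and TIP2;2 (402 ± 36.5 against 1090 ± 309 CPM). Of 24 ABA-responsive genes 3 were lower (3 adjusted over the list alone): ERD10 (142 ± 12.9 against 328 ± 60.9 CPM), LEA14 and ATHB7. AT5G63195 had counts in both libraries against 0 in WT (at least 49.2-fold), MIR398c at 7.17 ± 7.54 CPM against 0 counts (at least 15-fold), and AT1G25472 at 3.27 ± 2.31 against 0.0358 ± 0.0715 CPM. The first negative differences were in AT4G04223 (0.0681 ± 0.0963 against 6.46 ± 6.75 CPM), U3B (1.04 ± 0.606 against 39.3 ± 13.8 CPM) and U3D (3.34 ± 2.9 against 110 ± 33.4 CPM). None of 35 photosynthesis genes passed (0 adjusted over the list alone), with a median of -2.63. These lists had in camera an adjusted p = 2.25e-07 for aquaporins, 0.0314 for ABA-responsive genes and 4.13e-05 for photosynthesis; with an estimated correlation the adjusted p = 0.811, 0.812 and 0.976. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 2112 genes were higher and 2142 lower, 4254 in all. The count was 1 with the ERCC share as a covariate, 2 without PLC7-OE root drought 1, 1954 without PLC7-OE root drought 2, and 2616 without WT root drought 4. With the replicate number as a block it was 2718.

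In shoots all 4 overexpressors held less photosynthesis transcript than WT under drought. Of 35 genes 24 were lower in PLC2-OE, 29 in PLC3-OE, 34 in PLC5-OE and 34 in PLC7-OE, and 0 higher in each (25, 31, 35 and 34 adjusted over the list alone). LHCB2.1 stood at 4530 ± 2250 CPM in WT (n = 4), 1160 ± 133 CPM in PLC2-OE, 727 ± 380 CPM in PLC3-OE, 273 ± 155 CPM in PLC5-OE and 291 ± 104 CPM in PLC7-OE (n = 3 each). Camera gave an adjusted p = 5.84e-06, 3.27e-12, 9.62e-28 and 5.87e-17 in that order; with an estimated correlation the adjusted p = 0.785, 0.557, 0.51 and 0.473. With the ERCC share as a covariate 0, 4, 34 and 30 of the genes were lower. Of 20 aquaporins 13, 13, 12 and 14 were lower (13, 14, 12 and 15 adjusted over the list alone), with TIP2;2 at 327 ± 114 CPM in WT and 82.2 ± 16, 68.5 ± 3.56, 80.1 ± 25.7 and 53.7 ± 9.05 CPM in the lines. Their adjusted p = 3.28e-05, 4.94e-09, 9.19e-08 and 9.94e-08 in camera; with an estimated correlation the adjusted p = 0.657, 0.443, 0.51 and 0.473. Of 11 sulfur deficiency genes 7 were lower in PLC2-OE, 8 in PLC3-OE and 5 in PLC5-OE (8, 9 and 7 adjusted over the list alone), with APR3 at 126 ± 44.6 CPM in WT and 29.3 ± 5.69, 42.8 ± 8.51 and 47.1 ± 13.6 CPM in the lines. Their adjusted p = 0.00194, 4.44e-05 and 0.00338; with an estimated correlation the adjusted p = 0.657, 0.443 and 0.615. The sulfur list of PLC7-OE shoots was not called.

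PLC2-OE drought shoots differed from WT in jasmonate genes, with a wide spread between libraries. Of 22 jasmonate genes 12 were higher and 0 lower (13 adjusted over the list alone), among them JAZ9 (167 ± 201 against 12.4 ± 1.23 CPM, n = 3 and 4), LOX4 (158 ± 216 against 12.1 ± 8.81 CPM) and JAZ7 (18.7 ± 28.9 against 0.197 ± 0.155 CPM). Without PLC2-OE shoot drought 2 their differences of 3.75, 3.67 and 6.36 on the log2 scale were 2.03, 1.43 and 3.14. Camera gave the list an adjusted p = 0.0442, and adjusted p = 0.801 with an estimated correlation. The cell wall gene TCH4 stood at 274 ± 130 against 7.1 ± 6.86 CPM. Higher too were MRD1 (28.6 ± 2.93 against 0.0672 ± 0.134 CPM), ARO3 (3.93 ± 2.56 CPM against 0 counts, at least 4.88-fold) and AT4G26095 (3.71 ± 2.99 CPM against 0 counts, at least 4.6-fold). AT5G07842 and AT5G50150 had 0 counts in PLC2-OE (at least 18.8-fold and 10.3-fold lower), AATP1 stood at 0.0299 ± 0.0517 against 8.44 ± 14.3 CPM, and DREB1A was lower by 5.02 on the log2 scale. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4161 genes were higher and 3724 lower, 7885 in all, and the count was 1426 with the ERCC share as a covariate.

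PLC3-OE drought shoots had lower dehydration and wax transcripts than WT. Of 25 ABA-responsive genes 7 were lower (7 adjusted over the list alone), with KIN2 at 722 ± 150 against 2870 ± 1570 CPM (n = 3 and 4) and RD22 at 469 ± 154 against 1200 ± 174 CPM. Of 14 cuticular wax genes 5 were lower (5 adjusted over the list alone), with LTPG1, a lipid transfer protein gene, at 86 ± 33.9 against 255 ± 55.1 CPM and CER1, which makes wax alkanes, at 16.1 ± 10.7 against 60.9 ± 37.1 CPM. Of 15 phosphate starvation genes 4 were lower (4 adjusted over the list alone), led by SPX1 (2.16 ± 0.586 against 12 ± 3.67 CPM). Of 19 salicylate genes 2 were higher (0 adjusted over the list alone), PR5 (1120 ± 229 against 297 ± 400 CPM) and PR1 (856 ± 103 against 118 ± 205 CPM). PLC3, MRD1 (34.7 ± 6.77 against 0.0672 ± 0.134 CPM) and ARO3 (5.56 ± 3.73 CPM against 0 counts, at least 6.9-fold) were higher, and MPC (0.233 ± 0.116 against 14.6 ± 14.8 CPM), ORA47, a jasmonate response factor (0.575 ± 0.126 against 19.8 ± 21.1 CPM), and DREB1A (1.55 ± 0.438 against 45.8 ± 33.3 CPM) lower. These lists had in camera an adjusted p = 0.00182 for ABA-responsive genes, 0.00738 for wax, 0.0262 for phosphate and 0.0254 for salicylate; with an estimated correlation the adjusted p = 0.605, 0.443, 0.443 and 0.718. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2767 genes were higher and 2336 lower, 5103 in all. The count was 1403 with the ERCC share as a covariate, where the ABA-responsive call was lost (adjusted p = 0.212), and 2618 and 3367 without PLC3-OE shoot drought 1 and 2.

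PLC5-OE drought shoots differed from WT in clock genes. Of 19 clock genes 7 were lower and 5 higher (9 and 5 adjusted over the list alone), with PRR5 at 17.7 ± 2.77 against 108 ± 18.5 CPM, FKF1 at 40.9 ± 2.38 against 121 ± 20.9 CPM and BOA at 24.9 ± 0.811 against 2.63 ± 1.7 CPM (n = 3 and 4). PLC5, AT4G26095 (3.57 ± 2.01 CPM against 0 counts, at least 4.43-fold) and ARO3 (2.52 ± 2.5 CPM against 0 counts, at least 3.13-fold) were higher, as was the amylase gene AMY1 by log2 3.68. AT1G78170 had 0 counts in PLC5-OE against 16.6 ± 5.95 CPM (at least 41.9-fold lower), CIPK20 stood at 0.164 ± 0.0932 against 26.4 ± 15.2 CPM, AT2G29300 at 0.0246 ± 0.0426 against 2.12 ± 1.71 CPM, and DREB1A at 1.3 ± 0.593 against 45.8 ± 33.3 CPM. Camera gave the clock list an adjusted p = 0.0278, and adjusted p = 0.51 with an estimated correlation. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment found that 2211 genes were higher and 2104 lower, 4315 in all. The count was 3044 with the ERCC share as a covariate, 924 with these groups fitted alone, 2780 without WT shoot drought 3 and 1389 without PLC5-OE shoot drought 2.

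PLC7-OE drought shoots had lower dehydration and wax transcripts and higher senescence transcripts than WT. Of 25 ABA-responsive genes 15 were lower (15 adjusted over the list alone), with RD29A at 223 ± 41.2 against 916 ± 427 CPM and KIN2 at 403 ± 81.4 against 2870 ± 1570 CPM (n = 3 and 4). Of 14 wax genes 7 were lower (7 adjusted over the list alone), with LTPG1 at 71.3 ± 10.3 against 255 ± 55.1 CPM. Of 13 senescence and chlorophyll breakdown genes 5 were higher (5 adjusted over the list alone), among them PAO, a chlorophyll breakdown gene (51 ± 1.64 against 28.4 ± 1.95 CPM), and SAG21 (675 ± 135 against 174 ± 192 CPM). Of 19 salicylate genes 5 were higher and 2 lower (3 and 1 adjusted over the list alone), with PR5 at 1640 ± 395 against 297 ± 400 CPM and NIMIN1, a regulator of the salicylate response, at 8.68 ± 1.16 against 30.9 ± 20.6 CPM. Of 19 clock genes 7 were lower and 4 higher (8 and 4 adjusted over the list alone), with LNK1 at 8.8 ± 1.09 against 33.2 ± 9.66 CPM. ARO3 (8.11 ± 1.05 CPM against 0 counts, at least 10.1-fold), MRD1 (27.9 ± 1.23 against 0.0672 ± 0.134 CPM), AT4G26095 (6.04 ± 2.23 CPM against 0 counts, at least 7.49-fold) and PLC7 were higher, and the defensin gene PDF1.2c stood at 93.8 ± 37.4 against 2.32 ± 2.55 CPM. MAPR2 (0.0909 ± 0.0233 against 26.7 ± 28.1 CPM), CIB1 (0 counts against 3.03 ± 2.56 CPM, at least 8.62-fold lower) and AT2G44130 (0.156 ± 0.271 against 28.3 ± 21.4 CPM) were lower. Camera gave an adjusted p = 6.15e-05 for ABA-responsive genes, 0.023 for wax and for the clock, 0.0228 for senescence and 0.0484 for salicylate; the adjusted p = 0.473 with an estimated correlation for all of these but salicylate, at 0.81. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4088 genes were higher and 3689 lower, 7777 in all, and the count was 3421 with the ERCC share as a covariate.

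**Figure D3:**
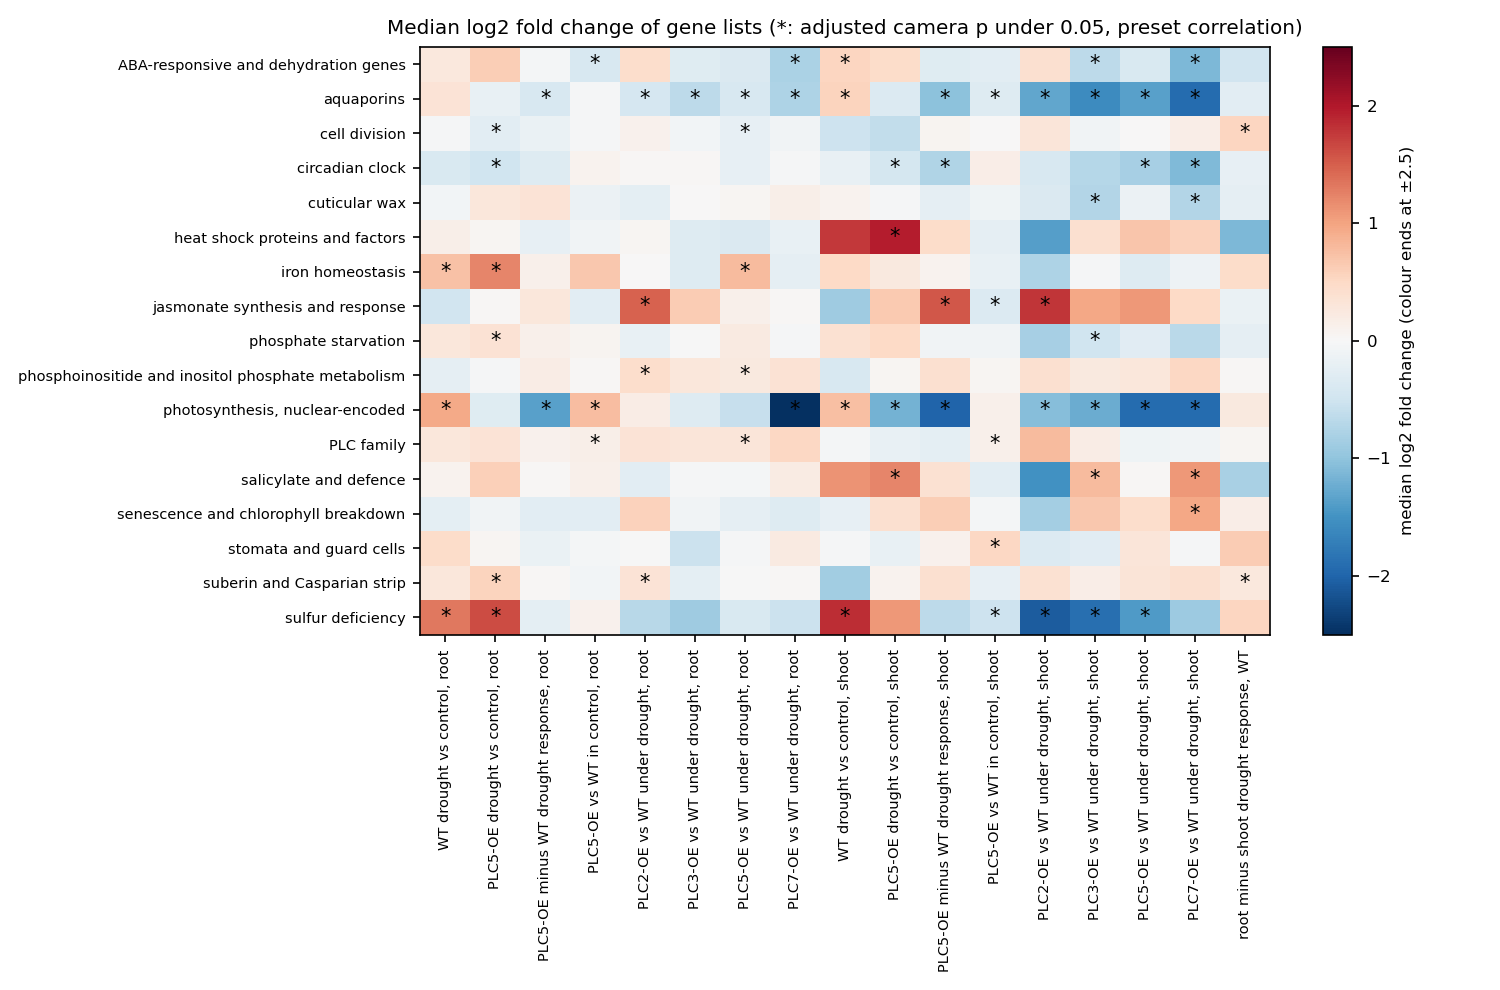
Median log2 fold change of the gene lists called in at least 1 comparison, by list and comparison, in colour, with the scale ending at ±2.5. Asterisks mark an adjusted camera p under 0.05 with the preset correlation, none of which held with an estimated correlation; photosynthesis and aquaporins are lower in the shoots of all 4 overexpressors under drought.

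The 4 overexpressors were also compared with each other under drought, in 1 test over all of them. It called 460 of 20505 genes in roots and 2255 of 19097 in shoots by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PLC2, PLC3, PLC5 and PLC7 were called in both tissues, with an adjusted p = 2.02e-08, 2.38e-11, 0.000769 and 0.00474 in roots, and PLC1 and PLC4 in shoots alone (adjusted p = 0.016 and 0.00384). The root count was 254 with the ERCC share as a covariate and between 136 and 334 as single libraries were left out. It was 811 with the replicate block, 1861 with DESeq2 and 2635 with these groups fitted alone. Root libraries that moved it by over 1.5 times were PLC2-OE 1, 2 and 3 (236, 161 and 136), PLC3-OE 3 (290), PLC5-OE 1, 2 and 3 (148, 228 and 289) and PLC7-OE 1 and 2 (187 and 229). In shoots they were PLC2-OE 1 and 2 (1192 and 712), PLC5-OE 3 (1278) and PLC7-OE 2 (1499).

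Part of the differences from WT was found in several lines, all of which were set against the same 4 WT libraries. In shoots 1275 genes were higher and 991 lower in all 4 lines, 2266 together, and in roots 71 and 58, 129 together. The largest overlaps were 4867 genes for PLC2-OE and PLC7-OE shoots (1610.1 for independent lists) and 3799 for PLC2-OE and PLC3-OE roots (761.4 for independent lists). Simulated unchanged lines shared 0 genes in each pair, and as that value leaves out the effects, it is no reference for these counts. With the WT libraries split between the lines the means were 2868 and 1072. The smallest was 171 for PLC2-OE and PLC5-OE roots (41.9 for independent lists). With the WT libraries split, PLC5-OE roots shared a mean of 50, 82 and 50 genes with PLC2-OE, PLC3-OE and PLC7-OE; the number for independent lists was not computed for the shorter lists of these splits. With the ERCC share as a covariate the root counts of PLC2-OE, PLC3-OE, PLC5-OE and PLC7-OE were 5, 2, 75 and 1. Across genes the covariance of the log2 fold changes lay between 0.28 and 0.51 in roots and between 0.56 and 0.96 in shoots. Simulated unchanged lines with shared controls gave 0.07 and 0.09. The simulation drew each gene independently, so it leaves out any shift that the WT libraries have in common, such as one linked to ERCC share. With the WT libraries split between the lines the covariance lay between 0.17 and 0.42 in roots and between 0.38 and 0.88 in shoots. Each part of the split keeps WT libraries of high ERCC share, so the split does not remove such a shift.

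The drought response of WT roots was finally set against that of WT shoots, to ask which genes answered differently in the organs. LSU1 responded more strongly in roots, by log2 4.52 ± 1.05, and so did CA2, a carbonic anhydrase gene (5.5 ± 0.82), and AT1G07730 (6.62 ± 1.67). The asparagine synthetase gene ASN1 had a root response higher by 4.11 ± 0.55. The largest negative differences were in DIR5, a dirigent protein gene (-6.3 ± 1.59), AT4G38340 (-5.35 ± 0.99) and AT3G20380 (-5.27 ± 1.12), and STP14 had -3.7 ± 0.51. None of 21 cell division genes passed (0 adjusted over the list alone), with a median of 0.53, and none of 22 suberin genes (2 adjusted over the list alone), with a median of 0.26. Camera gave these an adjusted p = 0.0312 and 0.0267, and an adjusted p = 0.709 with an estimated correlation for each. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 97 differences were positive and 108 negative, 205 in all of 21581 genes. The count was 110 and 119 without WT root control 1 and 4, and 508, 112 and 111 without WT shoot control 1, 3 and 4. It was 16 when these groups were fitted alone.

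The share of ERCC counts in a library went with the length of the transcripts it held. The slope of log2 level on log2 transcript length was lower in WT drought than in WT control libraries by 0.37 in roots and 0.47 in shoots, while the slope of the ERCC spike-ins on their own length differed by 0.15 and 0.08.

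**Figure D4:**
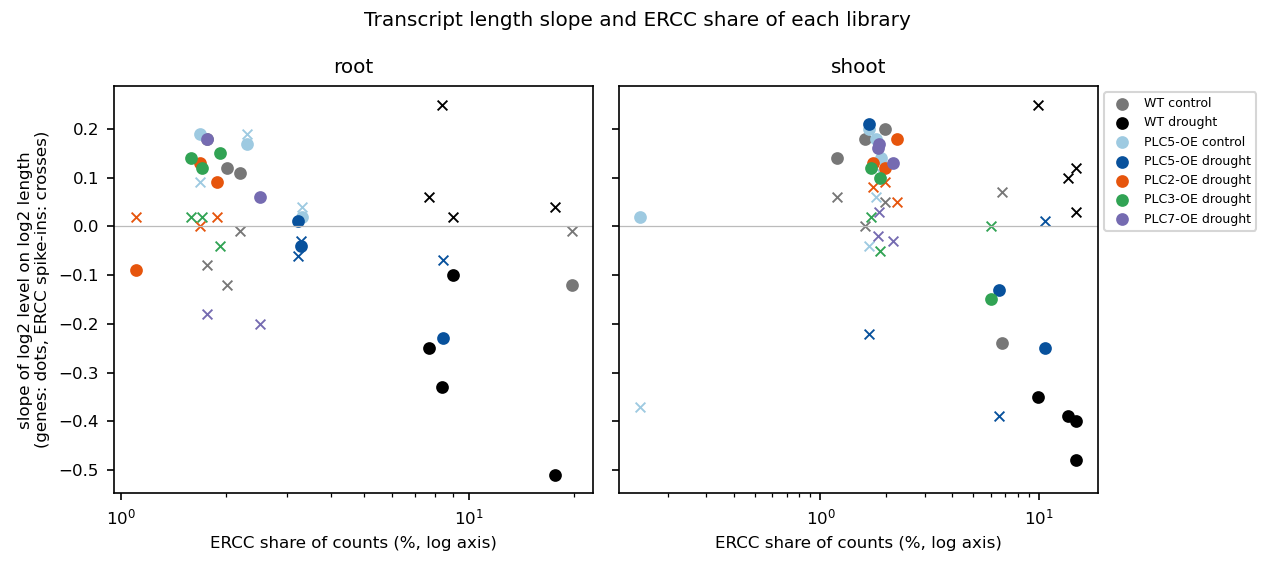
Slope of log2 level on log2 transcript length in each library, for genes (dots) and ERCC spike-ins (crosses), against the ERCC share of counts in percent on a log axis, for roots (left) and shoots (right), coloured by group. Libraries of high ERCC share have lower gene slopes, WT drought libraries among them, and the spike-in slopes do not follow.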

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

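The tests within control groups, of MRD1, of the summed PLC shares and with the ERCC share as a covariate were chosen only after the results were seen. Differences below were picked out because a library lay far from its group, because an effect differed between groups, or because a signal lay outside the gene counts. Of 55 combinations of a group and a measure examined for a distant library, 11 had one, and chance would give 2.8. Only groups of 4 libraries were examined, those of WT and PLC5-OE control shoots. No drought library of an overexpressor could therefore be picked out in this way. The 2.8 is no firm reference for the 11, because the measures come from the same libraries and some values lie near 0.

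The ERCC share lay apart from its group in PLC5-OE shoot control 4 (0.15%), WT root control 4 (19.73%), WT root drought 4 (17.71%) and WT shoot control 1 (6.74%). The share of 18S ribosomal RNA did so in WT shoot control 4 (8.18%) and WT shoot drought 1 (11.76%), and the photosynthesis list in WT shoot control 4 (11.36 log2 CPM). PLC7 did so in WT root drought 3 (118 CPM), and MRD1 in WT root drought 3 (51.4 CPM) and, at levels near 0, in PLC5-OE shoot control 3 (0.103 CPM) and WT shoot drought 3 (0.203 CPM). These MRD1 values are CPM without TMM scaling. In PLC5-OE control shoots and WT drought shoots the other libraries had 0 CPM of MRD1, so any count set a library apart. The ERCC counts themselves, outside the gene comparisons, had means of 10.7% in WT root drought and 13.26% in WT shoot drought.

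Tests of the difference itself picked out the interaction counts of 1 gene in roots and 1092 in shoots, and 205 between organs. In roots LNK1 had -1.45, aquaporins a median of -0.4 and photosynthesis -1.36. In shoots photosynthesis had -2, aquaporins -1.02, the clock -0.76 and jasmonate 1.55, and the first genes were CYP94B1 (9.31), AT4G11393 (6.79), ELI3-2 (5.87), CIPK20 (-7.81), AT2G29300 (-6.95) and AT5G35777 (-6.5). Between organs they were AT1G07730 (6.62), CA2 (5.5), LSU1 (4.52), DIR5 (-6.3), AT4G38340 (-5.35) and AT3G20380 (-5.27), with medians of 0.53 for cell division and 0.26 for suberin.

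The first pattern is the shift with transcript length in WT drought libraries, whose ERCC share is high. Library preparation that favours short molecules would move the spike-ins too. However, their slope differed by 0.15 in roots (95% interval -0.08 to 0.38, 49 targets) and 0.08 in shoots (-0.12 to 0.27, 31 targets), against -0.37 and -0.47 for genes. These intervals measure the scatter between targets and not between libraries. Spike-in slopes of single libraries were 0.02, 0.06, 0.25 and 0.04 in WT drought roots. In WT control roots they were -0.01, -0.08, -0.12 and -0.01. A library property that follows the ERCC share, and not drought itself, is a candidate explanation. Within control groups the change of each gene per unit of ERCC share was set against its WT drought fold. The rho across genes was 0.49 in roots and 0.38 in shoots, from 7 and 8 libraries. Most of the spread in ERCC share came from WT root control 4 (19.73%), WT shoot control 1 (6.74%) and PLC5-OE shoot control 4 (0.15%). With transcript length taken out of both sides rho was 0.4 and 0.41, so this agreement is largely apart from the length shift. WT root control 4 had a gene slope of -0.12. WT root drought 1 to 4 had -0.1, -0.25, -0.33 and -0.51, at 9%, 7.7%, 8.38% and 17.71% ERCC. Drought itself stays open, since PLC5-OE drought libraries under 5% ERCC differed from control in length slope by -0.14 in roots (-0.28 to 0, 2 libraries) and 0.08 in shoots (-0.09 to 0.24, 1 library). Drought libraries of PLC2-OE, PLC3-OE and PLC7-OE under 5% ERCC had gene slopes of -0.09 to 0.18 in roots and 0.1 to 0.18 in shoots (8 libraries each). WT drought libraries had -0.51 to -0.1 and -0.48 to -0.35, and control libraries under 5% ERCC 0.02 to 0.19 and 0.02 to 0.2. These 3 lines have no control libraries, so a drought effect that differs between genotypes is not excluded by them.

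The second pattern is a second overexpressed PLC in 2 root libraries. In WT root drought 3, a high PLC7 level of its own with no RNA of another line is argued against by MRD1, which stood at 83.7% of its PLC7-OE level, while other WT and PLC5-OE root libraries reached 0.131 CPM at most. PLC7 in that library stood at 65.1% of its PLC7-OE root level. Whether it holds RNA of a PLC7-OE plant stayed open over 3719 genes. There it lay at 0.17 between WT (0) and PLC7-OE (1), with other WT libraries from -0.165 to 0.214. That position cannot decide the question, because PLC7-OE and WT drought roots also differ in ERCC share. The share was 8.38% in this library, and 1.77% and 2.5% in the PLC7-OE roots. In PLC3-OE root drought 1 the PLC3 share of 0.567 and PLC5 share of 0.314 sum to 0.88, as a mixture of PLC3-OE and PLC5-OE RNA would give. MRD1, which is near 0 in PLC5-OE libraries, stood there at 56.8% of its mean in the other PLC3-OE roots. No biological explanation was tested.

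The third pattern is the lower photosynthesis response of PLC5-OE shoots. Transcript length is argued against as the whole cause: 31 of 31 genes kept the interaction with its trend removed. All 31 kept it with the ERCC share as a covariate, but few libraries set that slope, so the share stays open. Another time of harvest stays open: across 24 shoot libraries within groups the photosynthesis mean and the clock difference had r = 0.16 (interval -0.33 to 0.58, permutation p = 0.537) and rho = 0.19 (permutation p = 0.436), and r = -0.06 without the 2 farthest libraries, in 1 relation tested. The value lies below the bound set of 0.2 and its interval does not. An effect of PLC5 may also be present and was not separated from it.

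In several comparisons no other split of the libraries called as many genes as the labelled grouping. They were WT drought in roots (5882 genes, highest other split 4490, 1 of 35 as large) and shoots (6608 and 3126), and PLC5-OE drought in shoots (4064 and 164). PLC2-OE, PLC3-OE and PLC5-OE against WT in roots had 5051 and 3629, 6181 and 4722, and 340 and 306. PLC2-OE, PLC3-OE and PLC7-OE in shoots had 7885 and 4508, 5103 and 4963, and 7777 and 6732. Differences among lines in shoots had 2255 and 1853. With 35 splits the lowest share possible is 1 of 35, and nothing was corrected for the number of comparisons. Chance is therefore not excluded. In these comparisons of a line with WT, the highest other split kept the line's libraries together and moved 1 WT library to their side. Such a split keeps most of the labelled contrast, so a close second count does not make chance likelier. For PLC5-OE roots the count also moved widely with single libraries left out, as given above. For control roots (4 genes, highest other split 3, 1 of 35 as large) nothing is concluded, because PLC5 itself is 1 of the 4 and the count was 0 without libraries over 5% ERCC. Other splits called as many genes or more for the root interaction (1 gene, highest other 333, 12 of 50 splits as large) and the shoot interaction (1092 and 2563, 6 of 50). They did so too for control shoots (2 and 3, 2 of 35), PLC5-OE against WT in drought shoots (4315 and 4923, 2 of 35) and the comparison of organs (205 and 6351, 8 of 50). Chance cannot be excluded for any of these. For PLC5-OE against WT in drought shoots, the highest other split only moved WT shoot drought 4 to the PLC5-OE side. For the shoot interaction it only exchanged WT shoot control 1 and PLC5-OE shoot control 1. These 2 splits keep most of the labelled grouping, so their counts cannot speak for chance. The high counts of other splits of the root interaction and the organs point to a structure of the samples; for the organs, that split nearly mirrors treatment in roots. For PLC5-OE drought in roots the 10 splits are too few for a share as low as 1 of 35 (1530 genes, highest other 0).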

How the results depend on the processing

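The ERCC share as a covariate, the removed length trend, the omission of libraries over 5% ERCC and the omission of both libraries with a second PLC were chosen only after the results were seen. The second table of each sample holds the same quantification and was not run as an alternative. Counts below are genes with an adjusted p under 0.05 by edgeR's quasi-likelihood test unless DESeq2 is named, and cover those that moved by over 1.5 times. The cause was not tested, except that leaving out groups or libraries lowers the residual degrees of freedom and a 2-fold limit is stricter by construction. In both organs, PLC2-OE, PLC3-OE and PLC7-OE drought libraries lay below all WT drought libraries in ERCC share. With the share as a covariate these contrasts keep little information, so their lower counts do not show that the share is the cause.

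With only the groups compared in the fit, WT drought gave 2238 genes in roots and 4328 in shoots, PLC5-OE drought in roots 846, the root and shoot interactions 0 and 547, PLC5-OE in control roots 1, PLC2-OE, PLC5-OE and PLC7-OE against WT in roots 3094, 45 and 1875, PLC3-OE and PLC5-OE in shoots 2253 and 924, the lines in roots 2635, and the organs 16. DESeq2 gave 2303 for PLC5-OE drought in roots, 91 and 1805 for the root and shoot interactions, 26 and 5 for PLC5-OE in control roots and shoots, 864 for PLC5-OE against WT in roots, 1861 and 3766 among the lines in roots and shoots, and 434 between organs. RLE size factors and length offsets gave 0 and no filter gave 7 for the root interaction, where 1678 genes had an unadjusted p under 0.05.

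With a 2-fold limit WT drought gave 1939 and 3410 genes in roots and shoots, PLC5-OE drought 933 and 2329, and PLC2-OE, PLC3-OE, PLC5-OE and PLC7-OE against WT 1906, 2307, 223 and 1855 in roots and 4750, 2901, 2460 and 4689 in shoots. With the ERCC share as a covariate WT drought gave 915 and 860, PLC5-OE drought 932 and 734, the root interaction 4, control roots 10, PLC2-OE, PLC3-OE, PLC5-OE and PLC7-OE in roots 5, 2, 75 and 1, PLC2-OE, PLC3-OE and PLC7-OE in shoots 1426, 1403 and 3421, and the lines in roots 254.

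With ERCC scaling WT drought gave 17585 and 17776 genes, 52 and 9 of them up, PLC5-OE drought 173 and 13329, the interactions 34 and 17, control roots and shoots 32 and 9, PLC2-OE, PLC3-OE and PLC7-OE in roots 19921, 19715 and 18251, the 4 lines in shoots 16791, 16396, 13540 and 17707, the lines among themselves in shoots 69, and the organs 20. It moved the median of all genes by -2.17 and -3.34 for WT drought and -1.15 and -2.68 for PLC5-OE drought. Values of single genes under it were taken relative to that median and were not tested. With the length trend removed WT drought in roots gave 3764, the root interaction 0, and PLC3-OE and PLC7-OE in roots 3889 and 2374. Without libraries over 5% ERCC control roots and shoots gave 0 and 4 and PLC5-OE drought in shoots 2341. Without both libraries with a second PLC the root interaction gave 4, and PLC3-OE and PLC5-OE in roots 3474 and 89.

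With the replicate number as a block the counts that moved were 8 for control roots, 2718 for PLC7-OE in roots and 811 among the lines in roots.

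Single libraries left out gave 3517 to 7382 genes for WT drought in roots and 4930 to 7695 in shoots, 647 to 1805 and 2229 to 4535 for PLC5-OE drought, 0 to 27 and 227 to 2941 for the interactions, and 1 to 17 and 2 to 2 for control. For PLC2-OE, PLC3-OE, PLC5-OE and PLC7-OE against WT the ranges were 2535 to 5674, 3954 to 6615, 29 to 639 and 2 to 5034 in roots, and 6178 to 7731, 2618 to 6292, 1389 to 5712 and 5964 to 8476 in shoots. Among the lines they were 136 to 334 and 712 to 2787, and between organs 110 to 508. The lowest or highest count came without WT root drought 4 (3517), PLC5-OE root drought 1 (647), PLC5-OE shoot drought 3 (2229), WT root control 4 (27), PLC5-OE shoot drought 2 (227 and 1389), WT shoot drought 4 (2941), PLC5-OE root control 2 (17), PLC2-OE root drought 1 (2535), PLC3-OE root drought 3 (3954), PLC5-OE root drought 3 (29), WT root drought 2 (639), PLC7-OE root drought 1 (2), PLC3-OE shoot drought 1 (2618), PLC2-OE root drought 3 (136), PLC2-OE shoot drought 2 (712), WT root control 1 (110) and WT shoot control 1 (508). With 1 library left in PLC7-OE roots, that library is assumed to vary like the other groups.

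With WT libraries split between the lines, the overlaps of PLC2-OE with PLC3-OE, PLC5-OE and PLC7-OE averaged 1072, 50 and 609 in roots and 1735, 1134 and 2868 in shoots, those of PLC3-OE with PLC5-OE and PLC7-OE 82 and 954 in roots and 1011 and 2140 in shoots, and that of PLC5-OE with PLC7-OE 50 and 1684.

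Of 68 list calls 0 held with an estimated correlation, 64 with the replicate number as a paired block, 58 with the ERCC share as a covariate and 58 with the length trend removed. Calls lost with the covariate were PLC5-OE against WT in control roots (photosynthesis) and control shoots (aquaporins, jasmonate, sulfur), PLC2-OE and PLC5-OE roots (aquaporins; phosphoinositides), WT drought in shoots (ABA-responsive, aquaporins), PLC3-OE shoots (ABA-responsive) and the organs (cell division). With the length trend removed they were WT drought in roots (photosynthesis) and shoots (ABA-responsive, aquaporins), PLC2-OE roots (aquaporins, phosphoinositides), PLC5-OE roots (phosphoinositides, PLC family), PLC7-OE roots (ABA-responsive), PLC5-OE drought in shoots (clock) and control shoots (sulfur). The block lost control roots (photosynthesis), control shoots (sulfur), PLC2-OE roots (suberin) and PLC3-OE shoots (phosphate). Of 679 values of single genes 648 kept direction and call with DESeq2, 677 with RLE size factors, 492 with the ERCC covariate (185 lost the call) and 647 with the length trend removed; of 5628 values with a library left out, 5052 did. Direction reversed for PLC7 in PLC2-OE and PLC3-OE roots against WT, from -2.95 and -3.53 to 0.95 and 0.37 without WT root drought 3 (lowest -3.36 and -3.94, without WT root drought 4) and to 0.95 and 0.49 without both libraries with a second PLC. U3B in PLC2-OE and PLC3-OE roots went from -3.76 and -3.35 to 0.12 and 0.12 with the ERCC covariate.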

Other observations

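The genes below were chosen only after their values were seen, and the values are given without an explanation.

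Some genes of copper proteins were looked up by hand in PLC5-OE drought roots, and no list of them was tested. CSD1, a cytosolic copper/zinc superoxide dismutase gene, stood at 67.7 ± 24.1 CPM against 319 ± 85.6 CPM in WT drought roots (SD, n = 3 and 4), CSD2 at 30.7 ± 8.74 against 107 ± 27.6 CPM, and their copper chaperone gene CCS at 18.5 ± 3.89 against 44.9 ± 8.8 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these had an adjusted p = 0.000384, 0.00075 and 0.00501. MIR398c, precursor of a microRNA that targets these genes, stood at 33.3 ± 9.87 CPM there, 4.62 ± 3.3 CPM in WT control roots and 0 in WT drought roots. In the same test MIR398c was also higher than WT in PLC2-OE, PLC3-OE and PLC7-OE drought roots (adjusted p = 0.0234, 0.00722 and 0.0219). CSD1, CSD2 and CCS did not pass in those lines. In WT roots MIR398c, CSD1 and CCS fell with drought (adjusted p = 0.0218, 0.0235 and 0.00437), and CSD2 did not pass. In WT shoots CSD1, CSD2 and CCS had drought changes of -2.08, -2.46 and -2.51 on the log2 scale. In roots the interaction of genotype and drought did not pass for CSD1, CSD2, CCS or MIR398c (adjusted p = 0.0748, 0.0748, 0.14 and 0.143). MIR398c did not pass for drought against control in PLC5-OE roots (adjusted p = 0.0632). The copper transporter gene COPT2 stood at 6.38 ± 0.926 against 2.74 ± 3.15 CPM and did not pass (adjusted p = 0.23).

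The gene AT1G78170 stood at 0.0207 ± 0.0415 CPM in PLC5-OE control shoots (n = 4) and at 0 counts in PLC5-OE drought shoots (n = 3), against 6.27 ± 1.77 and 16.6 ± 5.95 CPM in WT. It was also lower than in WT in drought shoots of PLC2-OE, PLC3-OE and PLC7-OE, by 2.81, 1.93 and 2.09 on the log2 scale (adjusted p = 4.06e-05, 0.00139 and 0.000252 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). AT5G50150 stood at 0.0811 ± 0.071 CPM in PLC2-OE drought roots (n = 3) against 21.4 ± 7.6 CPM in WT. In CPM without TMM scaling, MRD1 stood at 26.2 CPM or more in the libraries of PLC2-OE, PLC3-OE and PLC7-OE. It stood at 0.28 CPM or less in those of WT and PLC5-OE, except WT root drought 3.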
